A study of Mus musculus with 10 samples.

How the data were processed

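The samples were epithelial cells of mouse intestine that carried 2 fluorescent reporters. In the Lgr5 reporter line, green fluorescent protein (GFP) is driven by the promoter of Lgr5, a receptor that marks the stem cells at the base of intestinal crypts. In the Ki67 reporter line, a red fluorescent protein is fused to the Ki67 protein, which is present in cycling cells and absent from resting ones. Fluorescence-activated sorting gave 4 groups, which combined high or medium GFP with high or low red fluorescence. The groups were Lgr5-high Ki67-high (2 arrays), Lgr5-high Ki67-low (2 arrays), Lgr5-medium Ki67-high (4 arrays) and Lgr5-medium Ki67-low (2 arrays). Total RNA was hybridised to Affymetrix Mouse Gene ST 1.1 arrays, which carry 1 sample per array, per the labels and the design text.

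The deposited value table holds 1 value per probe set and array, for 35556 probe sets on 10 arrays. The submitters' processing notes name MAS5 and GCOS, without a version or a role. MAS5 relies on mismatch probes, which this array type lacks, so the program that made the deposited values is not known. The background correction, the summary of probes into probe sets, the normalization and the log base are not given in the sources used here. The deposited values lie between about 1.16 and 13.8 on every array and were read as log2 values for that reason. If the log base were another one, the differences would change in unit, while their direction and tests would not. Array medians over all probe sets lay between 4.23 and 4.40, and upper quartiles between 7.04 and 7.10. The values were therefore used as deposited, without further normalization. No signal over background could be computed, because background values were not used here.

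Genes were named through the platform's gene table, whose annotation dates from 2016, and Entrez numbers were checked against the mouse RefSeq gene table of assembly GRCm38.p6, which was used for names only. In the table, 21218 probe sets have 1 gene symbol, 1881 have several, and the other 12457 are unnamed here. Of the named probe sets, 21185 matched by Entrez number and 0 symbols changed. A gene with several probe sets (1386 genes) was represented by the one with the highest mean over the arrays, which left 18820 genes. Probe sets with several symbols were used only in an alternative that took every row of the table.

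Expression was compared with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 10 arrays (6 residual degrees of freedom), so that the groups share 1 estimate of the spread, and the moderated test of eBayes was applied. The comparisons were Ki67 low against Ki67 high at each Lgr5 level, Lgr5 high against Lgr5 medium at each Ki67 level, the average of each pair of comparisons, and the interaction, which is the Ki67 difference at Lgr5 high minus that at Lgr5 medium. Differences are log2 values given as Ki67 low minus Ki67 high, or Lgr5 high minus Lgr5 medium, where 1 is a 2-fold difference. P-values were adjusted by Benjamini-Hochberg over the 18820 genes within each comparison, with a threshold of 0.05 and no minimum fold. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a difference was 0.13 in the comparison of the Lgr5-high groups and 0.11 in that of the Lgr5-medium groups.

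Before the data were examined, 28 gene lists were fixed. They covered stem cell markers, cell cycle phases, signalling pathways, metabolism, stress, the cell types of the intestinal epithelium, and immune and stromal cells that a sort gate could hold. Of their 835 entries, 754 were measured; the Paneth cell list (14 of 26) and the homologous recombination list (24 of 32) had the smallest shares of their members measured. Each list was tested with limma's camera, which asks whether its members differ more than other genes do, at a preset correlation between genes of 0.01 and with adjustment over the 28 lists. Camera with an estimated correlation and limma's fry were run beside it. Members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. Where a list passed camera, its median, its mean and the test had the same sign. A list score is the mean, over the members, of a gene's deviation from its mean over the 10 arrays.

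The genes to be named were also set by a rule before the data were examined. For each comparison of 2 groups they were the 10 genes with the largest difference in each direction among those past the threshold, with a mean in the higher group above the median of all genes (5.06) and no overlap between the arrays of the 2 groups. For the averaged comparisons and the interaction, 5 genes were taken in each direction; each list gave up to 4 members with the smallest p-values, and Lgr5 and Mki67 were always included. Predicted genes, receptor families and immunoglobulin segments were counted but not named. A gene named outside the rule is marked as chosen after its values were seen.

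The model was tested on simulated values for the same 18820 genes, with 200 of them changed. The changed genes were drawn from those above the median level, and the simulated noise was normal and independent between genes. With 200 changed genes the adjusted threshold is easier to reach than where few genes pass. The shares below therefore do not carry over to the real Lgr5-high comparison, where 1 gene passed. In the comparison of the Lgr5-high groups it recovered 74.6% of genes changed by 1 log2 unit, 37.3% of those changed by 0.5 and 93.9% of those changed by 2. In the comparison of the Lgr5-medium groups the shares were 83.6%, 38.8% and 97.0%. False calls made up 5.52% and 5.19% of the calls in these comparisons.

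The alternatives fixed before the data were examined were quantile normalization, centring of each array on its median, leaving out the dimmest 30% of genes, the mean of all probe sets of a gene, every row of the table, a variance trend with robust estimation, array weights, fits of only the 2 groups compared, the replicate number as a block, calls of at least 2-fold, and each array left out in turn. Where this left a group with 1 array, that array was assumed to vary like the other groups. Plots were drawn with matplotlib 3.10.9.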

Results

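Gene expression was measured in 4 sorted populations of mouse intestinal crypt cells, on 10 arrays in all. Lgr5-high cells correspond to the crypt base columnar stem cells that the study set out to divide into fast and slow cycling fractions by their Ki67 reporter level. Lgr5-medium cells have a lower Lgr5 reporter level. Replicate arrays within a group correlated at a mean of 0.992 to 0.998 across probe sets, and no 2 replicate arrays held identical values. Lgr5-medium Ki67-high replicate 4 had the lowest mean correlation with the other arrays (0.989) and the lowest array weight (0.294). That array also had the highest values of the T cell genes Gzma (7.47) and Cd3g (5.55) among the 10 arrays. Lgr5-medium Ki67-low replicate 2 had the highest values of the immune genes Ccl5 (7.45) and Gzmb (5.86). It also had the highest immune list score, 0.31 against 0.12 in the former array. These genes were chosen after their values were seen.

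The sort markers were examined first, as a check of the labels. Lgr5 (probe set 10372503) had a log2 expression of 9.38 ± 0.0077 (SD, n = 2) in Lgr5-high Ki67-high cells and 10.22 ± 0.29 (SD, n = 2) in Lgr5-high Ki67-low cells. It measured 7.39 ± 0.12 (SD, n = 4) in Lgr5-medium Ki67-high cells and 8.58 ± 0.25 (SD, n = 2) in Lgr5-medium Ki67-low cells. Lgr5 was thus higher in Lgr5-high cells by 1.99 among Ki67-high cells (limma adjusted p = 0.00104) and by 1.64 among Ki67-low cells (adjusted p = 0.00054). The rise from 7.39 to 8.58 between the Lgr5-medium fractions also passed (adjusted p = 0.000986), while its difference of 0.84 among Lgr5-high cells did not pass the threshold (adjusted p = 0.598). Mki67 (probe set 10568714), which encodes Ki67, was at 10.18 and 10.08 in the Ki67-high and Ki67-low fractions of Lgr5-high cells, and at 10.08 and 9.79 in those of Lgr5-medium cells. Neither Mki67 difference, -0.11 and -0.29, passed the threshold. Without Lgr5-high Ki67-high replicate 1 the Lgr5 difference of 1.99 among Ki67-high cells missed it (adjusted p = 0.0626), and without Lgr5-medium Ki67-high replicate 4 the Mki67 difference at Lgr5 medium passed it (-0.37, adjusted p = 0.0463).

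**Figure D1:**
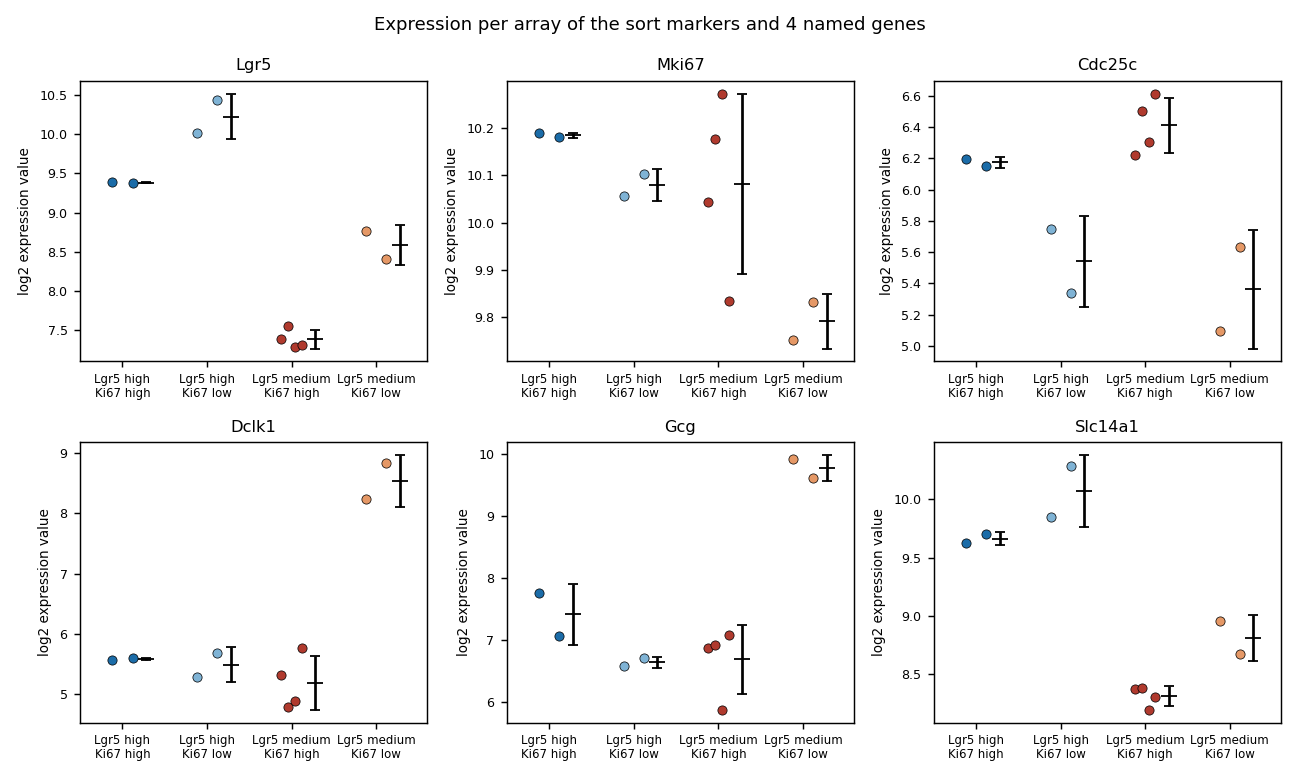
Log2 expression value per array (vertical axis) of Lgr5, Mki67, Cdc25c, Dclk1, Gcg and Slc14a1 in the 4 sorted groups (horizontal axis); each point is an array, and the line with bars is the group mean ± SD. Dclk1 averaged 8.54 in Lgr5-medium Ki67-low cells and 5.19 to 5.59 in the other groups, and the vertical axes do not start at 0.

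The Ki67-low and Ki67-high fractions of the stem cells were compared at Lgr5 high. Genes of G2 phase and mitosis lay lower in Ki67-low stem cells, with a median of -0.30 over the list and 40 of its 41 members below 0. Examples are Cenpe and Cenpf, which act at the kinetochores, the mitotic kinesin Kif23 and the cytokinesis factor Ect2, at -0.56, -0.71, -0.44 and -0.38. Genes of S phase and DNA replication lay higher instead, with a median of 0.24 and 36 of 41 members above 0, among them the replicative helicase subunit Mcm4 (0.41), the licensing factor Cdt1 (0.53) and the transcription factor E2f1 (0.59). The markers of crypt base columnar stem cells lay higher as well (median 0.34, 26 of 26 above 0), with Sp5, a Wnt-induced transcription factor, at 0.77 and Igfbp4 at 0.74. None of these single genes passed the threshold over all genes. Without Lgr5-high Ki67-low replicate 2 the S-phase median was 0.15 and the stem cell median 0.17.

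With p-values adjusted over the list alone, 17 G2/M genes fell, and 3 S-phase genes and 4 stem cell markers rose; over all genes the counts were 0, 0 and 0. These lists passed camera, at adjusted p-values of 7.73e-25 for G2/M, 3.74e-15 for S phase and 3.87e-14 for the stem cell markers. All 3 calls were lost with an estimated correlation (adjusted p = 0.143 with an estimated correlation for each). Fry called 0 of the 28 lists by direction; its smallest adjusted p was 0.0934. Altogether camera called 13 lists here, of which 8 passed in each of the 10 fits that left out 1 array.

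Wnt target and feedback genes had a median of 0.32 (20 of 21 above 0; adjusted p = 0.143 with an estimated correlation), and share members with the stem cell list, Lgr5, Sp5, Tnfrsf19, Axin2 and Ascl2 among them. Interferon and antigen presentation genes had a median of 0.28 (adjusted p = 0.157 with an estimated correlation), led by Cd74, the chaperone of class II antigen presentation molecules, at 0.79. Markers of differentiated secretory cells lay lower: the goblet list had a median of -0.31 and the enteroendocrine list one of -0.23, with the hormone genes Gip and Cck at -1.05 and -0.93 (adjusted p = 0.342 and 0.157 with an estimated correlation). Without Lgr5-high Ki67-low replicate 2 the Wnt median was 0.18 and the goblet median -0.46, and without replicate 1 of that group the goblet median was -0.20 and the interferon median 0.13, which was 0.19 without Lgr5-high Ki67-high replicate 2. Adjusted over the list alone, 3 Wnt genes, 1 interferon gene, 1 goblet gene and 0 enteroendocrine genes passed, against 0 of each list over all genes. Immediate early genes, which respond to cell dissociation, had a median of 0.30 (adjusted p = 0.622 with an estimated correlation). Their list score was 0.42 in Lgr5-high Ki67-low replicate 2 and 0.061 in replicate 1 of the same group, and their median was 0.15 without replicate 2.

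Of 18820 genes, 1 passed the threshold in this comparison, the retinol dehydrogenase pseudogene Rdh18-ps, which was higher by 1.64 ± 0.16 (SE) in Ki67-low cells (limma adjusted p = 0.0219). Its mean rose from 3.40 to 5.04, which is under the level set for naming, so it was chosen after its values were seen. At an unadjusted p under 0.05 there were 853 genes, where chance gives 941. The count of called genes was 0 without Lgr5-high Ki67-high replicate 1, without either Lgr5-high Ki67-low array and without any 1 of Lgr5-medium Ki67-high replicates 1, 2 and 3, and it was 4 without Lgr5-high Ki67-high replicate 2. It was also 0 when only these 2 groups were fitted and when every row of the table was tested.

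In the same comparison among Lgr5-medium cells, markers of tuft, enteroendocrine and goblet cells were far higher in the Ki67-low fraction. Of 28 tuft cell markers 24 rose, with a median of 2.49, and of 43 enteroendocrine markers 34 rose, with a median of 1.60. The tuft genes with the largest differences were the signalling regulator Rgs13 (3.66 ± 0.62, SE), the kinase Dclk1 (3.34 ± 0.27), the leukotriene enzyme Alox5 (3.30 ± 0.29), the adaptor Sh2d7 (3.19 ± 0.38) and the taste-pathway channel Trpm5 (3.16 ± 0.29). The largest enteroendocrine differences were those of the hormone genes Gcg (3.08 ± 0.31) and Sst (2.99 ± 0.37), encoding glucagon-family peptides and somatostatin. Goblet cell markers were higher too, 19 of 23, including the mucin Muc2 (1.49), Clca1 (1.48) and Bcas1 (1.76).

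The early secretory list, with 9 of 17 members higher and a median of 1.06, included the enteroendocrine fate regulators Neurog3 (1.76) and Rfx6 (2.60) and Insm1 (1.38). Of 14 measured Paneth cell markers 9 were higher (median 1.29). Without Lgr5-medium Ki67-low replicate 1 the early secretory median was 0.54 and the Paneth median 0.79. Adjusted over the list alone, the counts were 25 tuft, 41 enteroendocrine, 21 goblet, 14 early secretory and 12 Paneth genes. With an estimated correlation the enteroendocrine, tuft and goblet calls held (adjusted p = 0.00536, 0.0314 and 0.0314). Those of the early secretory and Paneth lists did not (adjusted p = 0.0572 and 0.12 with an estimated correlation). Absorptive enterocyte markers had a median of 0.21, with 1 of 46 members past the threshold both over all genes and adjusted over the list alone (adjusted p = 0.584 with an estimated correlation). The enterocyte call was lost without Lgr5-medium Ki67-high replicate 3 (median 0.091) and without Lgr5-medium Ki67-low replicate 2 (0.031), and the median was 0.34 without replicate 1 of the latter group. Immune cell markers had a median of 0.17, and the lysosomal protein gene Laptm5 rose by 0.63 (list adjusted p = 0.225 with an estimated correlation). In this list 1 gene rose and 1 fell over all genes, and 6 rose and 1 fell adjusted over the list alone. The immune median was 0.50 without the dimmest 30% of genes, 0.29 over members held by 1 list alone and 0.31 with the replicate number as a block. The stromal list had a median of 0.041 and did not pass camera (adjusted p = 0.085), although its member Vim, which encodes the filament protein vimentin, rose by 2.50.

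Genes of G2/M fell in Lgr5-medium Ki67-low cells: 35 of 41 passed over all genes and 41 adjusted over the list alone, with a median of -0.67. Among the largest were Cdkn3 (-1.10 ± 0.25, SE), the mitotic entry phosphatase Cdc25c (-1.05 ± 0.17), the spindle protein Hmmr (-1.04 ± 0.15) and Aurora kinase A, Aurka (-0.92 ± 0.12). Proliferation-linked chromatin genes fell as well, 6 of 19 over all genes and 12 adjusted over the list alone, including the condensin subunits Smc2 (-0.43) and Smc4 (-0.40). Both calls held with an estimated correlation (adjusted p = 0.0314 for each). S-phase genes had a median of -0.064, with 1 of 41 past the threshold over all genes (Dbf4, an activator of replication origins, at -0.52) and 2 adjusted over the list alone (adjusted p = 0.507 with an estimated correlation). The S-phase median was -0.19 with arrays centred on their medians and -0.11 without Lgr5-medium Ki67-high replicate 1, and its camera call was lost without replicate 4 of that group (-0.057) and without Lgr5-medium Ki67-low replicate 2 (-0.046). That call was also lost after quantile normalization (-0.027) and with the replicate number as a block (-0.055). Of 24 cell cycle exit genes, 4 were higher, led by the CDK inhibitor Cdkn1c (1.02), and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.305 with an estimated correlation). The median of that list, 0.15, was 0.072 without Lgr5-medium Ki67-high replicate 4 and 0.051 without Lgr5-medium Ki67-low replicate 1, where its call was lost, 0.23 without Lgr5-medium Ki67-high replicate 2 and 0.32 without Lgr5-medium Ki67-low replicate 2. It was 0.020 with arrays centred on their medians, 0.097 with array weights and 0.092 with the replicate number as a block, where the call was lost. The stem cell markers had a median of 0.29, and 5 of 26 rose over all genes and 10 adjusted over the list alone, among them Lgr5, Cd24a (0.71) and Msi1 (0.74) (adjusted p = 0.12 with an estimated correlation).

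In all, 674 genes differed between the Lgr5-medium fractions in limma's test, 499 higher and 175 lower in Ki67-low cells, and 234 of them by at least 2-fold. The number was 373 when only these 2 groups were fitted and 352 with the replicate number as a block. Array medians over the genes tested were 0.13 higher in the Ki67-low arrays. The median difference of all genes was -0.019, so the typical gene did not show that gap. Centring each array on its median removed the gap from every gene and gave 417 higher and 767 lower. With this centring, the tuft and G2/M medians were 2.36 and -0.80 and those of the enteroendocrine and stem cell lists 1.47 and 0.16. The enterocyte and immune medians were 0.075 and 0.042, while the unfolded protein response list (0.11) and the brush border list (0.076) turned to -0.024 and -0.055. Without Lgr5-medium Ki67-low replicate 1 the number of called genes was 264. Immediate early genes had a median of 0.35, which was -0.054 (adjusted p = 0.871) without the same array, 0.69 without replicate 2 of that group and 0.15 without Lgr5-medium Ki67-high replicate 4. The unfolded protein response median was 0.0087 without Lgr5-medium Ki67-low replicate 1 and 0.21 without replicate 2, and the brush border median was 0.047 without Lgr5-medium Ki67-high replicate 4 and 0.056 without Lgr5-medium Ki67-low replicate 2. The unfolded protein response call was lost without that replicate 1, and the brush border call in both fits given here. The immediate early median was also 0.22 with arrays centred on their medians and 0.18 with array weights. The brush border median was 0.12 after quantile normalization, turned to -0.010 with the mean of probe sets and to -0.015 with every row of the table, and lost its call with array weights (0.054), with the replicate number as a block (0.039) and over members held by 1 list alone (-0.030). All 3 calls were lost with an estimated correlation (adjusted p = 0.507, 0.369 and 0.201 with an estimated correlation for the immediate early, unfolded protein response and brush border lists). Over all genes 0, 2 and 3 members of these lists rose, and 0, 5 and 3 adjusted over the list alone.

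**Figure D2:**
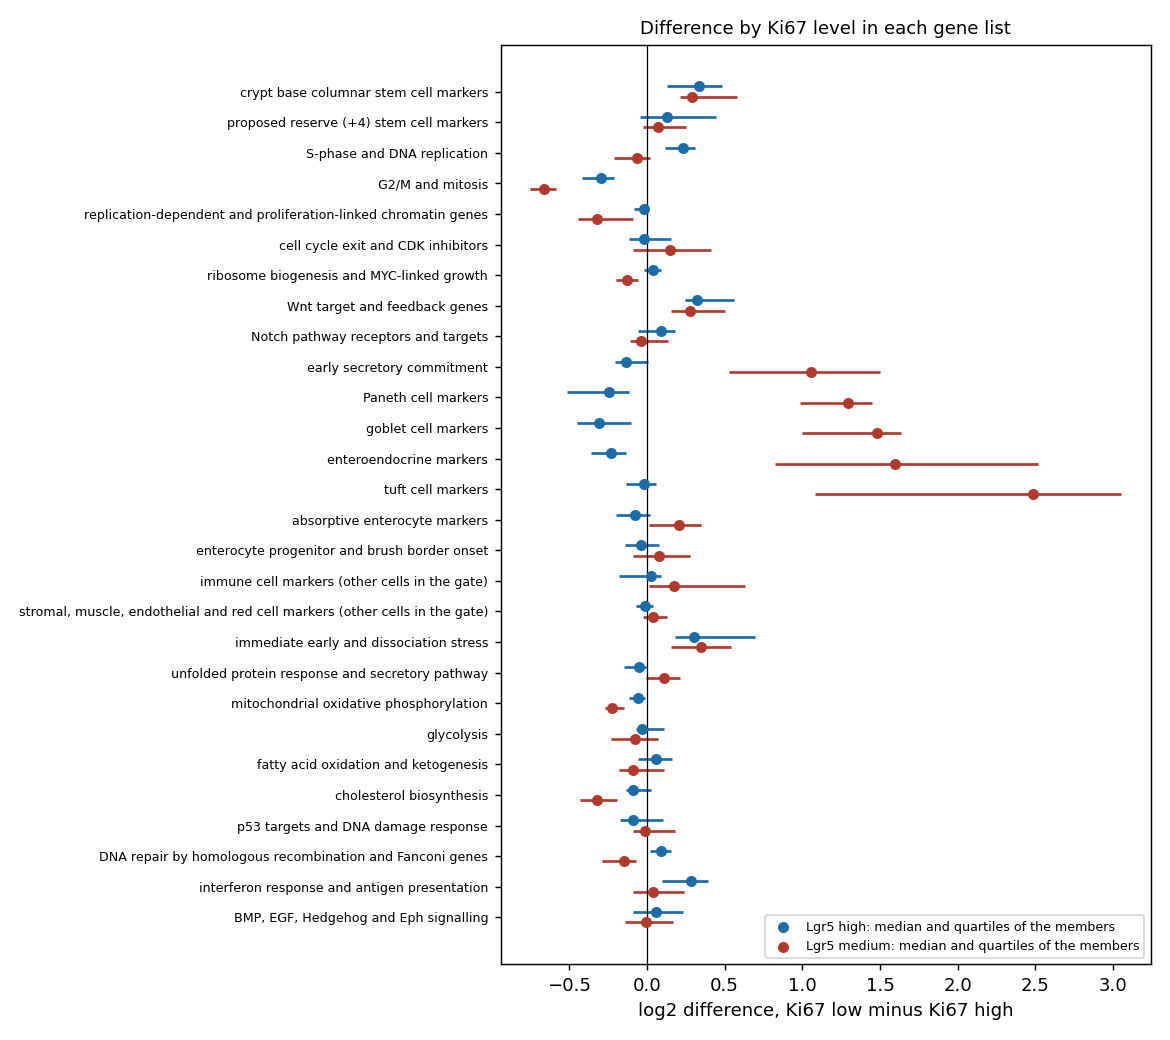
Log2 difference between Ki67-low and Ki67-high cells (horizontal axis) for each of the 28 gene lists (vertical axis), at Lgr5 high and at Lgr5 medium. Points are medians of the list's members and lines run from the lower to the upper quartile; the tuft list stands at -0.021 at Lgr5 high and at 2.49 at Lgr5 medium.

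Whether the Ki67 difference itself depended on the Lgr5 level was tested with the interaction. Enteroendocrine and tuft markers made up its largest named terms: the hormone genes Gip (-3.89 ± 0.48, SE), Ghrl (-3.88 ± 0.33), Gcg (-3.85 ± 0.47) and Cck (-3.45 ± 0.38), and the tuft gene Alox5 (-3.47 ± 0.44). The interaction was negative and past the threshold for 31 of 43 enteroendocrine, 17 of 28 tuft and 15 of 23 goblet genes, and for 40, 24 and 20 of them adjusted over the list alone. These 3 lists held with an estimated correlation (adjusted p = 0.00369, 0.036 and 0.036). In total 196 genes passed, 194 negative and 2 positive, the latter Rdh18-ps (1.19 ± 0.21) and Trip13 (0.77 ± 0.14), which encodes a mitotic checkpoint ATPase. S-phase and G2/M genes had positive medians, 0.32 and 0.39, with 0 members of either past the threshold over all genes or adjusted over the list alone (adjusted p = 0.115 and 0.15 with an estimated correlation). Without Lgr5-high Ki67-low replicate 2 the S-phase median was 0.21, and without Lgr5-medium Ki67-low replicate 1 the G2/M median was 0.25. The number of called genes was 79 and 117 without Lgr5-high Ki67-high replicates 1 and 2, and 86 and 124 without Lgr5-high Ki67-low replicates 1 and 2. It was 124 with every row of the table, 128 with the replicate number as a block and 299 with array weights.

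Across the 18820 genes, the Ki67 difference at Lgr5 high and that at Lgr5 medium, which share no array, correlated at Pearson's r = 0.0354 and Spearman's rho = 0.117; genes are not independent replicates. The r was -0.134 without Lgr5-high Ki67-low replicate 2 and 0.176 without replicate 1 of that group, and also fell below 0 without Lgr5-medium Ki67-high replicate 1 (-0.00214) and without Lgr5-medium Ki67-low replicate 1 (-0.0784). Of the 175 genes that fell at Lgr5 medium, 150 (85.7%) were below 0 at Lgr5 high, and of the 499 that rose, 192 (38.5%) were above 0.

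**Figure D3:**
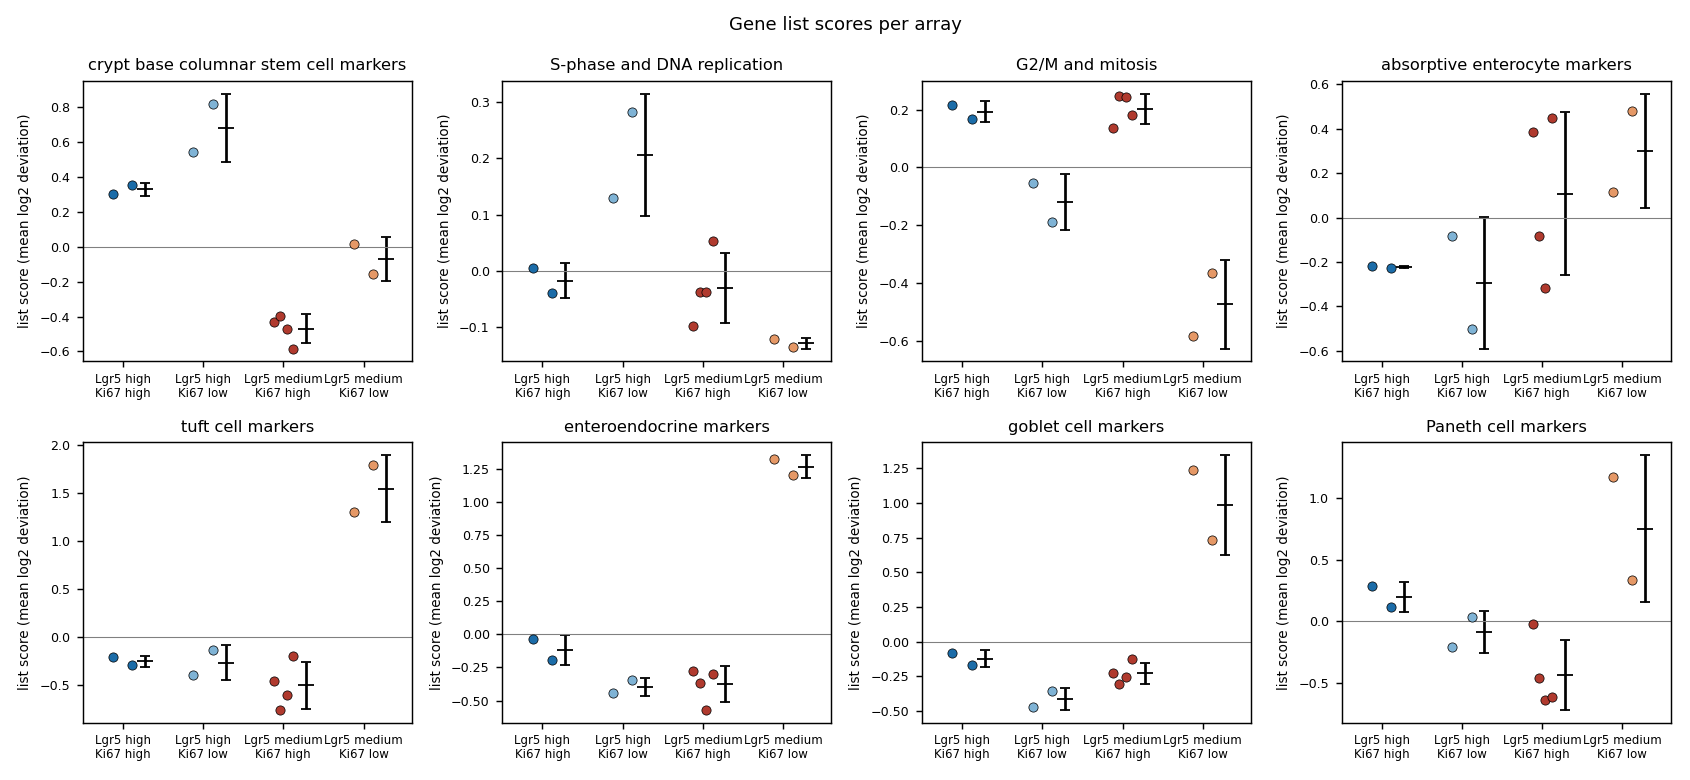
Gene list scores per array, as the mean log2 deviation of a list's members from their means over the 10 arrays (vertical axes), for 8 lists in the 4 sorted groups (horizontal axes). Each point is an array, the line with bars is the group mean ± SD, and the tuft score is 1.30 and 1.79 in the Lgr5-medium Ki67-low arrays and below 0 in all others.

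Stem cells were then compared with Lgr5-medium cells at equal Ki67 reporter level. Among Ki67-high cells, Lgr5-high cells had higher levels of the urea transporter Slc14a1 (1.35 ± 0.13, SE), the glutamate transporter Slc1a2 (1.67 ± 0.28), the cytoskeletal adaptor Sorbs2 (1.43 ± 0.13), the muscarinic receptor Chrm3 (1.32 ± 0.20), the secreted Wnt antagonist Sfrp5 (1.28 ± 0.14) and the BMP co-receptor Rgmb (1.26 ± 0.15). Prelp, Cttnbp2 and Kif12 were higher by 1.26 to 1.28. Of 26 stem cell markers 11 rose over all genes and 23 adjusted over the list alone, with a median of 0.85 (adjusted p = 0.114 with an estimated correlation). They included Tnfrsf19 (1.23) and Ascl2 (0.95), the latter a transcription factor of crypt base stem cells.

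Lower in these stem cells were the epithelial kinase Ptk6 (-1.29 ± 0.24, SE), Xkr9 (-1.16 ± 0.21), the antimicrobial lectin Reg3b (-1.05 ± 0.20), the GTPase Rnd2 (-1.01 ± 0.17), Phlda2 (-0.99 ± 0.10) and the lysophospholipid transporter Mfsd2a (-0.97 ± 0.17). Themis3, Acot9 and Mall were lower by between -0.97 and -0.91. Cholesterol biosynthesis genes were lower as a group, 5 of 19 over all genes and 19 adjusted over the list alone, with a median of -0.50. Examples are Msmo1 (-0.98 ± 0.13), Cyp51 (-0.89) and Sqle (-0.71), which encode enzymes of the sterol branch (adjusted p = 0.169 with an estimated correlation). Enterocyte markers had a median of -0.32, with 3 of 46 lower over all genes and 5 adjusted over the list alone (adjusted p = 0.36 with an estimated correlation). Glycolysis genes had a median of -0.26, with 1 of 18 lower over all genes (Pfkp, -0.72) and 6 adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). S-phase and G2/M genes had medians of 0.012 and -0.012 and did not pass camera (smaller adjusted p = 0.83).

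Markers of differentiated secretory cells lay higher in these stem cells: the Paneth list had a median of 0.72, the tuft list 0.29 and the enteroendocrine list 0.21 (adjusted p = 0.300, 0.595 and 0.250 with an estimated correlation). Their medians ranged from 0.58 to 0.86, from 0.21 to 0.37 and from 0.16 to 0.29 with 1 array left out, and these calls passed camera in each of the 10 fits. With arrays centred on their medians the enteroendocrine median was 0.13. Over all genes 0 members of each list passed, and 3, 0 and 0 adjusted over the list alone.

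Limma called 176 genes here, 98 higher and 78 lower (55.7% higher), against 81 and 120 with arrays centred on their medians and 67.1% higher after quantile normalization. With the replicate number as a block 6 genes were called, 4 of them among the 176; testing every row of the table gave 8, fitting only these 2 groups 107, and array weights 1135. The number was 0 without Lgr5-high Ki67-high replicate 1 and 4 without replicate 2 of that group; it was 27, 44 and 327 without Lgr5-medium Ki67-high replicates 2, 3 and 4, and 88 without either Lgr5-medium Ki67-low array.

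Among Ki67-low cells, Lgr5 had the largest rise at Lgr5 high of the genes named by the rule. It was followed by Gkn3 (1.54 ± 0.27, SE), the receptor gene Tnfrsf19 (1.36 ± 0.15), Ccdc3 (1.34 ± 0.24), Slc14a1 (1.26 ± 0.15), Sorbs2 (1.21 ± 0.15) and Cttnbp2 (1.21 ± 0.21). Next came the insulin-like growth factor binding protein Igfbp4 (1.11 ± 0.14), the acyl-CoA thioesterase Acot1 (1.07 ± 0.15) and Prelp (1.06 ± 0.23). Of 26 stem cell markers 10 rose over all genes and 22 rose and 1 fell adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 0.0395). The named genes with the largest falls at Lgr5 high belong to the tuft and enteroendocrine lists: Rgs13 (-3.27 ± 0.72), Alox5 (-3.08 ± 0.33), Dclk1 (-3.05 ± 0.31), Sh2d7, Sh2d6 and Trpm5 (-2.96 to -2.93) for the former, and Gcg (-3.12 ± 0.36), Ghrl (-3.00 ± 0.25), Cck (-2.99 ± 0.28) and the tachykinin gene Tac1 (-2.96 ± 0.41) for the latter. In these lists 21 of 28 tuft, 33 of 43 enteroendocrine and 18 of 23 goblet genes fell over all genes, and 24, 41 and 20 adjusted over the list alone. Each of these calls held with an estimated correlation (adjusted p = 0.0339, 0.00597 and 0.0339).

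Unfolded protein response and secretory pathway genes were lower in Lgr5-high Ki67-low cells (median -0.39, 6 of 37 over all genes and 20 adjusted over the list alone), among them the vesicle coat gene Sec24d (-1.23) and the oxidase Ero1b (-1.09); this call was lost with an estimated correlation (adjusted p = 0.0504 with an estimated correlation). The CDK inhibitor gene Cdkn1a fell by 1.10 on the log2 scale at Lgr5 high. Every S-phase and G2/M gene measured lay above 0, with medians of 0.36 and 0.36. Over all genes 2 and 1 of them passed, and 20 and 18 adjusted over the list alone (adjusted p = 0.0648 and 0.0892 with an estimated correlation). The S-phase median was 0.24 without Lgr5-high Ki67-low replicate 2.

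Here 534 genes were called by limma, 124 higher and 410 lower at Lgr5 high, against 253 and 328 with arrays centred on their medians. Without Lgr5-high Ki67-low replicates 1 and 2 the number was 341 and 198, without Lgr5-medium Ki67-low replicate 1 it was 271, and without Lgr5-medium Ki67-high replicate 4 it was 921. It was 318 with every row of the table, 803 with array weights and 274 when only these 2 groups were fitted. The replicate number as a block over the 10 arrays gave 502, 416 of them among the 534. A block on these 4 arrays gave 202 and one with the replicate numbers crossed 1238, alternatives chosen after the results were seen. Of the called genes, 42 were higher and 23 lower at Lgr5 high among Ki67-high cells as well; the means of these comparisons come from separate arrays, while their tests share 1 estimate of the spread per gene.

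Averaged over both Lgr5 levels, Ki67-low cells had higher levels of the homeobox gene Prox1 (1.16 ± 0.16, SE), the keratin Krt23 (1.08 ± 0.087), Lgr5 (1.02 ± 0.11), the calcium channel subunit Cacna1a (0.87 ± 0.12) and the transcription factor Runx1 (0.83 ± 0.088). Lower were Cdc25c (-0.84 ± 0.13), the cyclin Ccna1 (-0.78 ± 0.12), Hmmr (-0.78 ± 0.11), the DNA helicase Pif1 (-0.78 ± 0.14) and Efcab11 (-0.75 ± 0.14). Of 41 G2/M genes 27 fell over all genes and 40 adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation). The 233 called genes were 168 higher and 65 lower, against 140 and 101 with arrays centred on their medians. That number was 69, 31 and 30 without Lgr5-high Ki67-high replicates 1 and 2 and Lgr5-high Ki67-low replicate 2, 370 without Lgr5-medium Ki67-high replicate 4, and 133 and 381 without Lgr5-medium Ki67-low replicates 1 and 2. It was 104 with every row of the table and 530 with array weights.

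Averaged over both Ki67 levels, Lgr5-high cells had higher levels of Lgr5 (1.82 ± 0.11, SE), the cytochrome P450 gene Cyp2e1 (1.45 ± 0.25), Slc1a2 (1.44 ± 0.21), Gkn3 (1.40 ± 0.18) and Sorbs2 (1.32 ± 0.10). The phospholipase Pla2g10 (-1.24 ± 0.15), Tldc2 (-1.12 ± 0.18), Xkr9 (-1.09 ± 0.16), the sulfotransferase Chst4 (-1.04 ± 0.13) and the sulfate transporter Slc13a1 (-1.03 ± 0.20) were lower. For Pla2g10 and Chst4 the average rests mainly on the Ki67-low comparison. Pla2g10 averaged 5.01 and 5.27 at Lgr5 high and medium among Ki67-high cells, and 4.61 and 6.84 among Ki67-low cells. The same means of Chst4 were 5.93 and 6.36, and 5.87 and 7.52. Of 26 stem cell markers 20 rose over all genes and 24 adjusted over the list alone (adjusted p = 0.0562 with an estimated correlation), and of 46 enterocyte markers 11 fell over all genes and 26 adjusted over the list alone (adjusted p = 0.149 with an estimated correlation). Limma called 1115 genes, 452 higher and 663 lower at Lgr5 high. Their number was 384, 360 and 359 without Lgr5-high Ki67-high replicates 1 and 2 and Lgr5-high Ki67-low replicate 2, 668 and 696 without Lgr5-medium Ki67-low replicates 1 and 2, and 1708 without Lgr5-medium Ki67-high replicate 4. It was 628 with every row of the table and 1975 with array weights.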

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

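The tests of lineage genes, of slower cycling, of a lower stem cell share and of immune cells below were chosen only after the results they weigh were seen. So were the fits with 2 of the 4 Lgr5-medium Ki67-high arrays. An array far from the other 3 of its group was found for 3 of 91 gene and list values in Lgr5-medium Ki67-high cells, where chance gives about 1 in 20. They are Alox5 in replicate 4 (5.29, against a mean of 4.51 in the others), Krt23 in replicate 2 (5.61 against 5.28), and the score of the chromatin list in replicate 1 (-0.017 against 0.057).

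The difference between Ki67-low and Ki67-high cells depended on the Lgr5 level for 196 genes, by limma's test of the interaction. Of the 63 named genes 17 were among them. The tuft genes were Dclk1 (-3.44), Alox5 (-3.47), Sh2d7 (-3.34), Trpm5 (-3.24), Sh2d6 (-3.42), Fyb (-3.28) and Spib (-3.13). The hormone genes were Gcg (-3.85), Sst (-3.34), Ghrl (-3.88), Cck (-3.45), Tac1 (-3.08) and Gip (-3.89). The others were Krt23 (-0.99), Pla2g10 (-1.96), Rdh18-ps (1.19) and Trip13 (0.77).

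The interaction also passed camera for 18 lists, of which 3 hold with an estimated correlation, the tuft (median -2.43), enteroendocrine (-1.92) and goblet (-1.72) lists. Those that do not hold with it are the Paneth (-1.65), early secretory (-1.19), enterocyte (-0.30), cell cycle exit (-0.16), unfolded protein response (-0.15), brush border (-0.11) and immune (-0.085) lists, and with positive medians the G2/M (0.39), S-phase (0.32), homologous recombination (0.29), cholesterol (0.29), chromatin (0.28), ribosome biogenesis (0.19), oxidative phosphorylation (0.15) and fatty acid oxidation (0.15) lists. With arrays centred on their medians the enterocyte, cell cycle exit and unfolded protein response medians were -0.16, -0.015 and -0.0087, and the brush border and immune medians turned to 0.034 and 0.059. The chromatin, cholesterol, ribosome biogenesis and oxidative phosphorylation medians were then 0.42, 0.43, 0.34 and 0.30, and fatty acid oxidation lost its call (0.29, adjusted p = 0.124). That call was also lost after quantile normalization (0.11), with the replicate number as a block (0.11) and without the dimmest 30% of genes (0.15). Cell cycle exit lost its call with array weights (-0.13), with the block (-0.12) and over members held by 1 list alone (-0.14). Brush border lost its call with the block (-0.075) and over those members (-0.045), and its median was -0.056 with every row of the table, -0.053 with the mean of probe sets and -0.19 after quantile normalization. The immune call ended after quantile normalization (-0.018), and that median was -0.42 without the dimmest 30% of genes, -0.22 over members held by 1 list alone and -0.13 with the block. Quantile normalization gave a chromatin median of 0.18, and the early secretory median was -0.71 over members held by 1 list alone. Leaving out 1 array ended the calls of 6 of the 18: the enterocyte list without Lgr5-high Ki67-low replicate 2 (-0.062), Lgr5-medium Ki67-high replicate 3 (-0.15) or Lgr5-medium Ki67-low replicate 2 (-0.086); cell cycle exit without Lgr5-high Ki67-high replicate 1 (-0.18), Lgr5-medium Ki67-high replicate 4 (-0.12) or Lgr5-medium Ki67-low replicate 1 (-0.053); and brush border without Lgr5-high Ki67-low replicate 2 (-0.083), Lgr5-medium Ki67-high replicate 4 (-0.084) or Lgr5-medium Ki67-low replicate 2 (-0.057). The immune call ended without Lgr5-high Ki67-high replicate 1 (-0.073) or Lgr5-medium Ki67-low replicate 2 (-0.028), and that of oxidative phosphorylation without Lgr5-high Ki67-low replicate 1 (0.075) or Lgr5-medium Ki67-low replicate 1 (0.083). Fatty acid oxidation lost its call without Lgr5-high Ki67-high replicate 2 (0.12), Lgr5-high Ki67-low replicate 1 (0.094), Lgr5-medium Ki67-high replicates 2 (0.12) and 4 (0.13) or Lgr5-medium Ki67-low replicate 1 (0.070). Without Lgr5-medium Ki67-low replicate 1 the Paneth, early secretory, G2/M, cholesterol and immune medians were -1.02, -0.68, 0.25, 0.43 and -0.17. Without replicate 2 of that group the cholesterol, cell cycle exit and unfolded protein response medians were 0.13, -0.26 and -0.26. The enterocyte and immune medians were -0.53 and -0.051 without Lgr5-high Ki67-low replicate 1, the S-phase and immune medians 0.21 and -0.13 without replicate 2 of that group, the immune median -0.14 without Lgr5-medium Ki67-high replicate 2, and the oxidative phosphorylation median 0.10 without replicate 4 of the latter.

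The first pattern is that 1 gene passed the threshold for Ki67 level at Lgr5 high and 674 at Lgr5 medium (0 to 4 and 264 to 779 with 1 array left out; the lowest at Lgr5 medium was without Lgr5-medium Ki67-low replicate 1). Fewer arrays do not account for it, since a median of 457 genes (327 to 925) was called at Lgr5 medium with 2 of the 4 Ki67-high arrays. Replicate arrays did not spread more at Lgr5 high, where the median residual SD was 0.726 times that at Lgr5 medium. The test used 1 spread per gene shared by all groups, however. This ratio therefore does not decide whether the spread limited the calls at Lgr5 high. A candidate explanation is a rise of enteroendocrine, tuft, goblet and Paneth genes at Lgr5 medium that Lgr5-high cells lack. Of the 108 measured genes of these lists, 88.9% had a negative interaction at an unadjusted p under 0.05 in limma's test. Over all 18820 genes, 1520 reached that level in either direction. As 86 of the 108 were called higher at Lgr5 medium, the share restates the pattern and is no separate support. Of the 674 called genes, 86 belong to these lists. As the lists hold only 108 measured genes, this count does not show how much of the pattern the explanation covers.

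The second pattern is that S-phase genes lay higher and G2/M genes lower in Lgr5-high Ki67-low cells, list calls that are lost with an estimated correlation. Slower cycling that lowers genes of every phase alike would need an S-phase median below 0. The median was 0.24 (0.15 to 0.29 with 1 array left out), but this value belongs to the pattern itself and is no separate test. Sorting on the phase of the cycle may account for it, but the S-phase median at Lgr5 medium cannot decide this. The Ki67 fractions at Lgr5 medium also differ in tuft, enteroendocrine, goblet and chromatin genes, so that median need not reflect the phase alone. It was -0.064 (-0.11 to -0.046 with 1 array left out). That lies between the value set beforehand for such sorting, 0 or above, and the bound of -0.2 set against it. With arrays centred on their medians it was -0.19. Centring removed a gap of 0.13 between array medians, whereas the median difference of all genes was -0.019. A technical difference between arrays also stays open, since the groups differed in S-phase minus G2/M score by 1.85 times the largest gap between replicate arrays; that score was 0.18 to 0.47 in the 4 Ki67-low and -0.29 to -0.13 in the 6 Ki67-high arrays, but at Lgr5 medium mainly through G2/M scores of -0.58 and -0.37 against 0.14 to 0.25. With 2 arrays per group at Lgr5 high, sorting on the phase and a technical difference cannot be told apart.

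The third pattern is the rise of tuft, enteroendocrine, goblet and Paneth genes in Lgr5-medium Ki67-low cells. A lower share of stem cells that raises every other cell type alike is argued against by the enterocyte list. Its median of 0.21 was the highest among the enterocyte, immune and stromal lists. The highest of these medians lay -2.28 from the tuft median (-2.41 to -2.07 with 1 array left out). The immune list bears little weight here, as most of the immune genes given next were dim. Stem cell markers lay higher in this fraction, not lower, although that list call is lost with an estimated correlation. Their median was 0.27 to 0.40 with 1 array left out and 0.16 with arrays centred on their medians. Immune cells that carry the haematopoietic genes of the tuft list stay open, since of 10 immune genes only 3, Ccl5, Gzma and Cd74, lay above the median level of all genes, too few to decide, and their median lay -1.85 from the tuft median (-2.10 to -1.46). Lgr5-medium Ki67-low replicate 2 had both the highest immune list score (0.31) and the highest tuft score (1.79) of the 10 arrays. The 2 scores did not go together in every array, however. Replicate 1 of that group had an immune score of 0.10 and a tuft score of 1.30. Lgr5-medium Ki67-high replicate 4 had an immune score of 0.12 and a tuft score of -0.20. Dim probe sets and the normalization are argued against by the 86 called marker genes, of which 96.5% were still called after quantile normalization and 98.8% without the dimmest 30% of genes. A biological difference between the sorted fractions also stays open, and was not tested.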

How the results depend on the processing

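The block on crossed replicate numbers, the block on 4 arrays and the fits with 2 of the 4 Lgr5-medium Ki67-high arrays were chosen only after the results were seen. Each of 285 differences of named genes was recomputed under 18 or 19 alternatives, 10 of which left out 1 array; 0 changed sign in them, and 129 stayed past limma's threshold in all of those run. The cause was not tested where no cause is given. Signal over background could not be computed, so its limit on dim genes is not known; Lgr5 and Mki67 have 1 probe set each, and no linear scale was tried, since the values were already logarithmic.

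Testing every row of the table adds tests and also changes the moderated spread. The SE of the Lgr5 difference at Ki67 high, for example, was 0.138 in the main fit and 0.144 with every row. Every row gave 0 genes for Ki67 level at Lgr5 high and 8 and 318 for Lgr5 level at Ki67 high and low. It gave 104 and 628 for the averaged Ki67 and Lgr5 comparisons and 124 for the interaction. Array weights gave 1135 and 803 for Lgr5 level at Ki67 high and low, 530 and 1975 for the averaged comparisons and 299 for the interaction. Fits of only the 2 groups compared, with fewer arrays behind the spread, gave 0 and 373 for Ki67 level at Lgr5 high and medium and 107 and 274 for Lgr5 level at Ki67 high and low. The replicate number as a block gave 0 and 352 for Ki67 level, 6 for Lgr5 level at Ki67 high and 128 for the interaction. For Lgr5 level at Ki67 low that block gave 502 genes, a block on 4 arrays 202 and one with the numbers crossed 1238. Calls of at least 2-fold, a stricter criterion, numbered 234 for Ki67 level at Lgr5 medium, 23 and 220 for Lgr5 level at Ki67 high and low, and 36 and 70 for the averages. Centring arrays on their medians gave 1184 genes for Ki67 level at Lgr5 medium, and Lgr5-medium Ki67-high replicates 1 and 3, 1 and 4, and 3 and 4 alone gave 440, 327 and 332.

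With an estimated correlation, the called lists numbered 0 and 5 for Ki67 level at Lgr5 high and medium, 0 and 6 for Lgr5 level at Ki67 high and low, 1 and 1 for the averages and 3 for the interaction. Fry called 0 and 13 for Ki67 level, 5 and 16 for Lgr5 level at Ki67 high and low, 9 and 18 for the averaged Ki67 and Lgr5 comparisons and 8 for the interaction. The correlation of the Ki67 differences was -0.0031 with array weights and -0.0093 over genes called in either comparison.

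The brush border median for Ki67 level at Lgr5 medium turned to -0.055 with centring, -0.010 with the mean of probe sets, -0.015 with every row of the table and -0.030 over members held by 1 list alone. Centring also turned the medians of the unfolded protein response list at Lgr5 medium (-0.024), oxidative phosphorylation for Lgr5 level at Ki67 low (0.0014), S phase in the averaged Ki67 comparison (-0.0087), and the brush border (0.034) and immune (0.059) interactions. Every row of the table turned the interferon list in the averaged Lgr5 comparison (0.0069), and members held by 1 list alone turned the reserve list for Ki67 level at Lgr5 high (-0.016) and in the average (-0.0019).

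With each array left out in turn, the called genes ranged from 0 to 4 and from 264 to 779 for Ki67 level at Lgr5 high and medium, from 0 to 327 and from 198 to 921 for Lgr5 level at Ki67 high and low, from 30 to 381 and from 359 to 1708 for the averages, and from 79 to 292 for the interaction. The correlation ranged from -0.134 to 0.176, the Lgr5 difference at Ki67 high from 1.96 to 2.05 and the Mki67 difference at Lgr5 medium from -0.37 to -0.23. The list medians that changed sign were oxidative phosphorylation (-0.16 to 0.018) and homologous recombination (-0.0070 to 0.18) for Ki67 level at Lgr5 high, immediate early genes for Ki67 level at Lgr5 medium (-0.054 to 0.69) and oxidative phosphorylation for Lgr5 level at Ki67 low (-0.15 to 0.011).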

Other observations

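No test in this part was chosen after its result was seen. Proposed reserve stem cell markers, which label slowly dividing cells above the crypt base, had a median of 0.13 between the Ki67-low and Ki67-high fractions of Lgr5-high cells (adjusted p = 0.157 with an estimated correlation). That call was lost without Lgr5-high Ki67-high replicate 1 (0.11) and without Lgr5-high Ki67-low replicate 2 (0.070), and the median was 0.25 without replicate 1 of the latter group. Over members held by 1 list alone the call was lost too and the median turned to -0.016 (adjusted p = 0.374). Of 8 measured members 0 passed limma's threshold over all genes there and 2 adjusted over the list alone. In the average over both Ki67 levels, 2 of them rose at Lgr5 high over all genes, Lrig1 (0.57), a feedback inhibitor of EGF receptors, and the telomerase gene Tert (0.28), and adjusted over the list alone 5 rose and 1 fell (adjusted p = 0.0799 with an estimated correlation). Notch pathway genes followed with 3 of 15 higher over all genes and 4 adjusted over the list alone, among them the receptor Notch1 (0.71) and Olfm4 (0.36) (adjusted p = 0.0711 with an estimated correlation). Ribosome biogenesis genes had a median of 0.21 in that average, with 3 of 38 higher over all genes, including Myc (0.56) and the nucleolar protein gene Ncl (0.29), and 16 adjusted over the list alone (adjusted p = 0.0711 with an estimated correlation). The homologous recombination list, with 24 of its 32 members measured, had a median of 0.21, and 2 genes, Brca2 (0.45) and Topbp1 (0.32), rose over all genes and 11 adjusted over the list alone (adjusted p = 0.0734 with an estimated correlation). Both this average and that of ribosome biogenesis rest mainly on the Ki67-low comparison. Homologous recombination scores at Lgr5 high and medium were 0.060 and -0.010 among Ki67-high cells, and 0.15 and -0.19 among Ki67-low cells. With 1 array left out, the ribosome biogenesis median was 0.066 to 0.098 at Ki67 high and 0.22 to 0.30 at Ki67 low.

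In the same average, metabolic genes lay lower in Lgr5-high cells, although for oxidative phosphorylation and fatty acid oxidation this rests mainly on the Ki67-high comparison. Glycolysis genes had a median of -0.23, and 5 of 18 fell over all genes and 9 adjusted over the list alone, among them Pfkp (-0.70), Hk1 (-0.54) and Aldoa (-0.37), which encode enzymes of the pathway (adjusted p = 0.0711 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.14, with 41 of 42 below 0 and 0 past limma's threshold over all genes or adjusted over the list alone (adjusted p = 0.225 with an estimated correlation). Fatty acid oxidation genes had a median of -0.091, which was -0.050 after quantile normalization, although Acot1 rose by 0.82; that gene was the 1 past the threshold over all genes and adjusted over the list alone (adjusted p = 0.169 with an estimated correlation). Among Ki67-high cells the oxidative phosphorylation and fatty acid oxidation medians were -0.21 and -0.16 (adjusted p = 0.250 and 0.213 with an estimated correlation), with 0 members past over all genes and 0 and 1 adjusted over the list alone, the latter a rise. The first was -0.14 after quantile normalization, and the second -0.25 without Lgr5-high Ki67-high replicate 1, -0.28 without Lgr5-medium Ki67-high replicate 1, -0.25 with the mean of probe sets and -0.24 with every row of the table. Among Ki67-low cells the fatty acid oxidation list did not pass camera (median -0.021, adjusted p = 0.296), and oxidative phosphorylation had a median of -0.068 (adjusted p = 0.571 with an estimated correlation), with 0 members past over all genes or adjusted over the list alone. That call was lost without Lgr5-high Ki67-low replicate 2 (-0.0038) and without Lgr5-medium Ki67-low replicate 2 (0.011), after quantile normalization (-0.050) and without the dimmest 30% of genes (-0.068). Its median turned to 0.0014 with arrays centred on their medians, and was -0.15 without Lgr5-high Ki67-low replicate 1 and -0.14 without Lgr5-medium Ki67-low replicate 1. The interaction does not establish a difference between the Ki67 levels for either list (adjusted p = 0.531 and 0.396 with an estimated correlation).

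In the average over both Ki67 levels, the p53 target list did not pass camera (adjusted p = 0.567), and 2 of its 23 members fell over all genes and adjusted over the list alone, Cdkn1a (-0.80) and Perp (-0.30). The BMP, EGF, Hedgehog and Eph signalling list did not pass either (adjusted p = 0.383), and its members Efnb2 (-0.87) and Ihh (-0.61), encoding an ephrin ligand and Indian hedgehog, fell over all genes, while adjusted over the list alone 1 rose and 4 fell.

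Other splits of the arrays into groups of the same sizes were counted within the levels of the other marker, 90 in all for each averaged comparison. For Ki67 level, the real split gave 233 called genes and the highest of the others 197, so that 1 of the 90 splits, the real one, gave as many. For Lgr5 level, the real split gave 1115 called genes and the highest other 448, and again 1 split gave as many. Each count was thus reached by a share of splits under 0.05. For Ki67 level, every split with over 1 called gene kept the real grouping of the Lgr5-medium arrays. With that grouping kept, up to 197 genes were called under another Lgr5-high grouping, so chance is not excluded for Ki67 level at Lgr5 high. For Lgr5 level, every split with over 1 called gene kept or mirrored the real grouping of the Ki67-low arrays. For the number of called lists chance cannot be excluded: 6 splits gave as many as the real one for Ki67 level (17 lists, highest other 20) and 6 for Lgr5 level (22 lists, highest other 23). The correlation across genes of the Ki67 differences at the 2 Lgr5 levels, 0.0354, was reached in size by 70 of the 90 splits, with 0.427 as the highest other, so chance cannot be excluded.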
